A study of Mus musculus with 2 samples.

How the data were processed

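Both samples were total RNA of MEL cells treated with 2% DMSO for 5 days, and per the labels the fragments were selected at 300 to 350 bases. Each library came with a table of genes and a table of transcripts. Per the readme deposited with each sample, the authors used the mouse genome mm10 and the GENCODE annotation M4. The aligner, the quantification program and their versions are not given in the sources used here. Per the file headers, the authors' tables give for each gene an estimated count, which need not be a whole number, together with TPM, FPKM, a posterior mean and posterior standard deviation of the count, and a posterior mean TPM. In the tables as deposited, TPM has the same sum over all rows in both libraries, so every TPM depends on the short RNAs in the table. Per the file headers, the transcript tables add the percent of the gene's TPM that each transcript holds. FPKM as deposited by the authors was used only as an alternative to TPM.

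Each gene table held 43346 Ensembl gene rows, 26248 numbered tRNA rows and 97 spike-in rows. Gene names, types and coordinates came from the GENCODE M21 annotation on GRCm38, the same assembly coordinates as mm10 but a later annotation release than the authors used. Of the Ensembl rows, 42462 matched by gene identifier without its version and 884 did not. Coordinates are 1-based. Unmatched rows, tRNA rows and spike-in rows stayed in the TPM totals as the authors made them. For transcripts over 2000 nt, effective lengths in the tables were a median of 154 nt below the annotated lengths in replicate 1 and 161 nt below in replicate 2. The shortest RNAs kept an effective length of a few bases or 0. With an effective length of 0, 26 genes in replicate 1 and 49 in replicate 2 had 100 or more counts and a TPM of 0, the longest of them 132 nt and 136 nt.

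Estimated counts totalled 65109488 in replicate 1 and 90856320 in replicate 2. A count of 0 allows up to 3 counts, which is 0.0461 CPM in replicate 1 and 0.0330 in replicate 2. Such floors and all intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The libraries were first compared over genes by a chi-square statistic, which was 368 per degree of freedom. This rules out only that 1 library was deposited under both names. The label fields gave 1 group, and no comparison between groups was made.

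The spread between libraries was estimated with edgeR 4.0.16 (R 4.3.3) on estimated counts rounded to whole numbers, with TMM scaling, a model with the mean only, and genes with 10 or more counts in at least 1 library. Genes that differ between the libraries were found with an exact two-sided binomial test per gene on the same counts and scaling, with Benjamini-Hochberg adjustment, at an adjusted p under 0.05 and a difference of 2-fold or more. Log2 ratios of single genes used TMM-scaled counts with 0.5 added, and their 95% intervals are exact (Clopper-Pearson). Expressed genes were counted at a TPM of 1 or more in both libraries. Globin shares and ratios are sums of TPM, with the mean and SD of the libraries.

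Before the data were examined, 23 gene lists were fixed with 251 different gene symbols, of which 248 matched. Hbb-b1, Hbb-b2 and Ahsp did not match by name. Values of 2 list members are not reported here singly, though the members count in their lists. For the level of a list, its median TPM was placed among the medians of 10000 random lists of as many protein-coding genes with TPM above 0 in either library. For the difference between libraries, the median of log2 (TPM + 1) in replicate 2 minus replicate 1 was placed among 10000 random lists matched on mean expression, drawn from the 100 nearest genes for each member. A change on this scale understates that of low genes. The percentiles describe these libraries and are not tests between conditions. Transcript use was compared in genes with several transcripts at a TPM of 1 or more.

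The genes named in the text followed a rule fixed before the data were examined: members of the lists, with up to 5 in full, the 15 genes with the highest mean TPM, the 5 genes with the largest ratio in each direction among those that differ and have 100 or more counts in at least 1 library, and up to 5 genes whose leading transcript held the smallest share. The ranks of protein-coding genes and their types among the top 20, and the protein-coding genes in the top 15 by count, were added after the values were seen. A gene was called uncertain where the authors' posterior standard deviation exceeded 5% of its count in either library. Genes of the rRNA locus are those overlapping chromosome 17 from 39843013 to 39848827.

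Alternatives fixed before the data were examined were other TPM thresholds, FPKM, counts or posterior means in place of TPM, DESeq2 1.42.0 size factors or total counts in place of TMM, other count minimums, other pseudocounts, another pool for random lists, a rescaling of TPM and each library left out. Added after seeing the data were FPKM for the globin ratio, a globin share over genes of 200 nt or longer, and TMM-scaled counts for the list differences. The estimate of spread, the binomial test and the list differences were tested on simulated data. For 15272 genes, simulated coefficients of variation of 0.1, 0.2 and 0.4 were estimated as 0.0987, 0.199 and 0.397. In counts simulated with counting error only, the binomial test recovered 86 of 100 genes changed 2.5-fold and 96 of 100 changed 4-fold among 15272, with 1 false call. That simulation held no further spread between libraries, while the coefficient of variation estimated here was 0.215. Its number of false calls therefore does not carry over to these libraries. Of 100 lists of 12 genes with no shift, 6 lay outside the central 95% of random lists, and all 100 with a shift of 0.5 did. These lists were drawn at random from genes with a mean log2 (TPM + 1) above 1. The rates therefore need not hold for lists of other sizes, with members near 0 TPM or with members that vary together. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.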

Results

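Total RNA was profiled in MEL cells, a mouse erythroleukemia line whose cells resemble immature red cell precursors and which makes hemoglobin when exposed to dimethyl sulfoxide (DMSO). The cells had been kept in 2% DMSO for 5 days. The series held 2 libraries of this 1 condition, named replicate 1 and replicate 2 by the labels. Estimated counts summed to 65109488 in replicate 1 and to 90856320 in replicate 2. The labels call the libraries biological replicates but cite the same biosample record for both, so the spread between them may be partly technical. No untreated library was analysed here, and the comparisons below are between genes within the treated cells and between the 2 libraries. A test between conditions had no second group, and even 2 libraries against 2 could not have given an exact permutation p below 0.333.

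The first question was which RNAs the libraries of the treated cells held. The shares below are of counts assigned to the rows of the gene tables, so they need not be the shares of RNA in the cells. By the number of estimated counts, protein-coding genes took 67.2% ± 2.29 (SD, n = 2) of each library. Small structured RNAs, the group of 7SL, 7SK, snRNA, snoRNA, scaRNA, RNase P and RNase MRP RNA, took 22.8% ± 2.72 of the counts. 7SL, the RNA of the signal recognition particle, accounted for 13.1% ± 1.94 of the counts, and 7SK, which holds the elongation factor P-TEFb inactive, for 5.26% ± 0.335. On the TPM scale the order turned around: small structured RNAs held 84.7% ± 1.22 of the summed TPM and protein-coding genes 13.2% ± 0.388. snoRNA, which guide rRNA modification, held 30.0% ± 6.86 of the TPM against 1.93% ± 0.179 of the counts, and spliceosomal snRNA held 21.5% ± 6.99 against 1.27% ± 0.195. From replicate 1 to replicate 2 the snoRNA share of TPM fell from 34.9% to 25.2%. Its share of counts rose, from 1.80% to 2.05%. The snRNA shares rose from 16.6% to 26.5% of TPM and from 1.13% to 1.41% of counts.

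Among protein-coding genes, ribosomal protein genes took 5.90% ± 0.432 of all counts and replication histone genes 2.38% ± 0.566 (SD, n = 2). The 13 mitochondrial protein-coding genes took 0.701% ± 0.0108 of the counts. Genes overlapping the annotated rRNA locus on chromosome 17, together with annotated rRNA genes, differed most between the libraries among the classes above 5% of counts, with 5.05% ± 3.32. The rows for 97 spike-in sequences held 0 counts in both libraries, which allows up to 0.0461 CPM in replicate 1 and 0.0330 in replicate 2, from counting error alone.

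**Figure D1:**
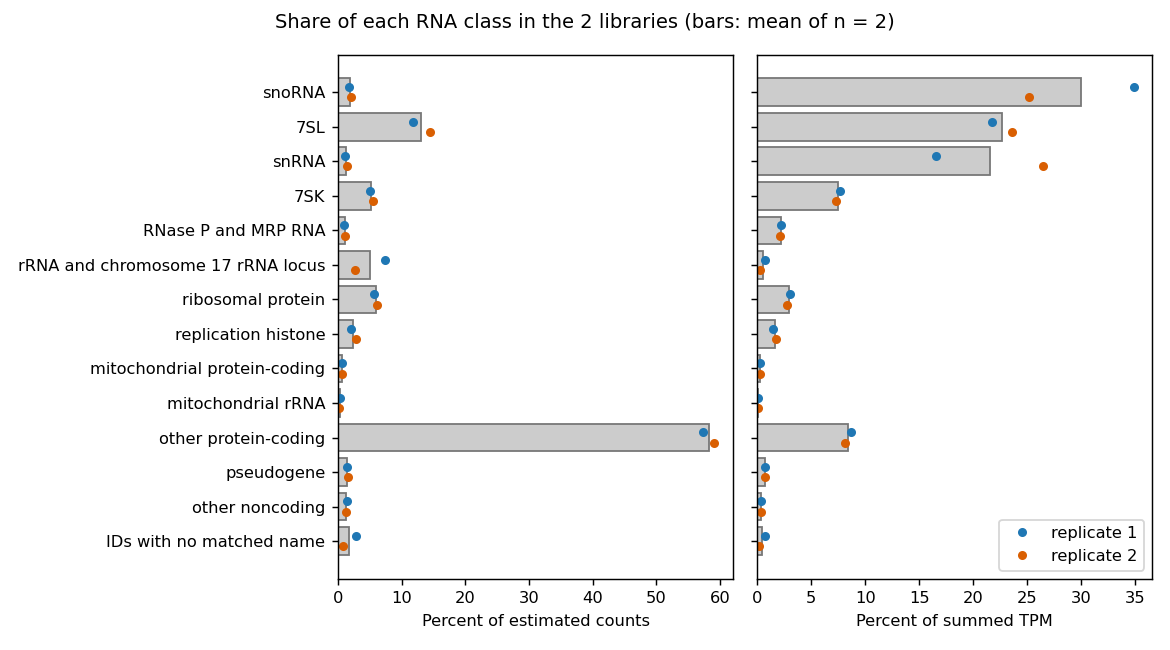
Percent of estimated counts (left) and percent of summed TPM (right) held by each RNA class; grey bars are the mean of the 2 libraries and the points are replicate 1 (blue) and replicate 2 (orange). Other protein-coding genes hold a mean of 58.3% of the counts and 8.42% of the TPM, while snoRNA hold 1.93% and 30.0%.

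The 15 genes with the highest mean TPM were all noncoding: 7 snRNA genes, 4 snoRNA genes, 3 genes of the 7SL and 7SK RNAs and 1 ribozyme. The 7SL genes Rn7s2 (chromosome 12, 69361182 to 69361481, GRCm38) and Rn7s1 (chromosome 12, 69159295 to 69159594) led with 113745 ± 6460 and 112638 ± 6692 TPM (SD, n = 2). Their sequences are near copies, and the split of reads between them is uncertain. Rn7sk (chromosome 9, 78175303 to 78175633) followed with 74859 ± 2418 TPM. Of the snoRNA genes, Gm25835 reached 53831 ± 9404 TPM, Snora73b 28044 ± 1008, Snord15b 22126 ± 6123 and Snora73a 16207 ± 762. The 7 snRNA genes, namely Rnu1a1, Gm25679, Gm22068, Gm22634, Gm23804, Gm22317 and Gm26444, were all 164 nt long and had mean TPM between 18038 and 21692. They lay between 12796 and 15110 TPM in replicate 1 and between 23280 and 29793 in replicate 2. The assignment of reads among them is uncertain as well. Rmrp, the RNA of the RNase MRP complex, stood at 18476 ± 138 TPM. The TPM of the shortest of these RNAs rests on an effective length near 0. By mean count, 6 of the top 15 genes were protein-coding: Eef1a1, Hba-a2, Hba-a1, Hbb-bs, the elongation factor gene Eef2 and the mitochondrial gene mt-Co1.

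The list of RNAs without a poly(A) tail or with a processed end, fixed in advance to describe a total RNA library, had a median of 687 TPM in replicate 1 and 878 TPM in replicate 2, at the 100th percentile of random protein-coding lists in both. All 14 members were at 1 TPM or more in both libraries. Malat1, a nuclear long noncoding RNA, stood at 287 ± 48.2 TPM (SD, n = 2), the replication histone genes Hist1h4d and Hist1h4c at 1132 ± 233 and 939 ± 229 TPM, and the telomerase RNA Terc at 58.3 ± 4.21 TPM. Neat1, the scaffold of nuclear paraspeckles, was the lowest member with 4.04 ± 0.276 TPM. Linker histones had a median of 121 TPM in replicate 1 and 148 TPM in replicate 2. Of these, Hist1h1a stood at 232 ± 71.7 TPM and H1f0, the linker histone that builds up in differentiating cells, at 25.7 ± 7.67 TPM, while H1fx was at 0 counts in both libraries.

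At a threshold of 1 TPM in both libraries, 8564 genes were expressed, of which 8003 were protein-coding, 233 were processed pseudogenes, 47 were snoRNA genes and 45 were lincRNA genes. Across the 8003 protein-coding genes, log2 TPM of the libraries had a Pearson correlation of 0.975 and a Spearman correlation of 0.960, as a description across genes, which are not independent replicates. The biological coefficient of variation of edgeR, fitted with the mean as the only term, was 0.215 over 15272 genes.

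The second question was how far the red cell programme, the known response of this line to DMSO, was present. Globin mRNAs were among the most abundant protein-coding transcripts of the cells by TPM. Hba-a2 (chromosome 11, 32296489 to 32297298), Hba-a1 (chromosome 11, 32283511 to 32284465) and Hbb-bs (chromosome 7, 103826534 to 103828096) had the highest mean TPM of protein-coding genes, with 4413 ± 2240, 2986 ± 1341 and 2105 ± 1183 (SD, n = 2). In replicate 1 Hbb-bs, with 1268 TPM, ranked behind the ribosomal protein gene Rplp1, the histone gene Hist2h2aa2 and the translation factor gene Eef1a1, with 1799, 1597 and 1445 TPM. Hbb-bt (chromosome 7, 103812524 to 103813996), the minor adult beta globin gene, stood at 359 ± 190 TPM. Of the 20 protein-coding genes with the highest TPM, 3 were globin genes, 6 replication histone genes and 9 ribosomal protein genes.

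The adult globins together held 0.986% ± 0.495 (SD, n = 2) of all TPM, with 0.636% in replicate 1 and 1.34% in replicate 2. The share depended on what it was taken from: it was 1.88% ± 1.11 of all estimated counts and 7.67% ± 4.04 of the TPM of nuclear protein-coding genes. The summed alpha globin TPM exceeded the summed adult beta globin TPM by a ratio of 3.08 ± 0.260, with 3.26 in replicate 1 and 2.89 in replicate 2. Within the beta locus, Hbb-bs was at 5.81 ± 0.225 times the TPM of Hbb-bt, and within the alpha locus Hba-a2 was at 1.46 ± 0.0966 times that of Hba-a1. Embryonic globins held 0.0304% ± 0.00370 of the globin TPM. The embryonic genes Hbb-y, Hbb-bh1 and Hba-x stood at 2.30 ± 1.68, 0.425 ± 0.163 and 0.370 ± 0.0283 TPM, and the list's median lay at the 19.4 percentile of random protein-coding lists in replicate 1 and the 26.2 percentile in replicate 2.

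Genes for the making of heme were expressed throughout. All 8 heme synthesis enzymes exceeded 1 TPM in both libraries, with a list median of 27.3 TPM in replicate 1 and 30.4 in replicate 2, at the 100th percentile of random lists. Alas2 (chromosome X, 150547375 to 150570638), the erythroid enzyme of the first step, had the highest mean with 120 ± 79.8 TPM (SD, n = 2), and Alad stood at 80.3 ± 16.6. In replicate 1 Alad was the higher of the pair, with 68.5 TPM against 63.2 for Alas2. The lowest was Uros, uroporphyrinogen synthase, with 5.58 ± 2.31 TPM, and Alas2 was at 20.2 ± 5.93 times its level. All 12 genes of iron and heme handling were also above 1 TPM, with a median of 15.4 TPM in replicate 1 and 8.16 in replicate 2. The ferritin chains Ftl1 and Fth1 led with 298 ± 61.7 and 184 ± 6.07 TPM, the transferrin receptor Tfrc stood at 39.7 ± 2.18 TPM, and Hmox1, which degrades heme, was the lowest with 1.62 ± 0.431 TPM.

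All 17 genes of the red cell membrane and skeleton were expressed, with a median of 13.3 TPM in replicate 1 and 17.1 in replicate 2, at the 100th percentile of random lists in both. Sptb, erythroid beta spectrin, stood at 40.5 ± 10.04 TPM (SD, n = 2), the blood group protein gene Icam4 at 38.4 ± 0.969, and Rhd at 36.4 ± 3.54. Slc4a1 (chromosome 11, 102348824 to 102366203), which encodes the anion exchanger band 3, was the lowest member with 3.66 ± 3.30 TPM. Of 14 measured genes of the red cell cytoplasm and of maturation, 11 were at 1 TPM or more in both libraries. Carbonic anhydrase Car1 stood at 203 ± 84.2 TPM, peroxiredoxin Prdx2 at 155 ± 40.4 and the erythropoietin receptor Epor at 30.8 ± 0.573. Alox15, the lipoxygenase of reticulocytes, was near 0 with 3 counts in replicate 1 and 5 in replicate 2.

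**Figure D2:**
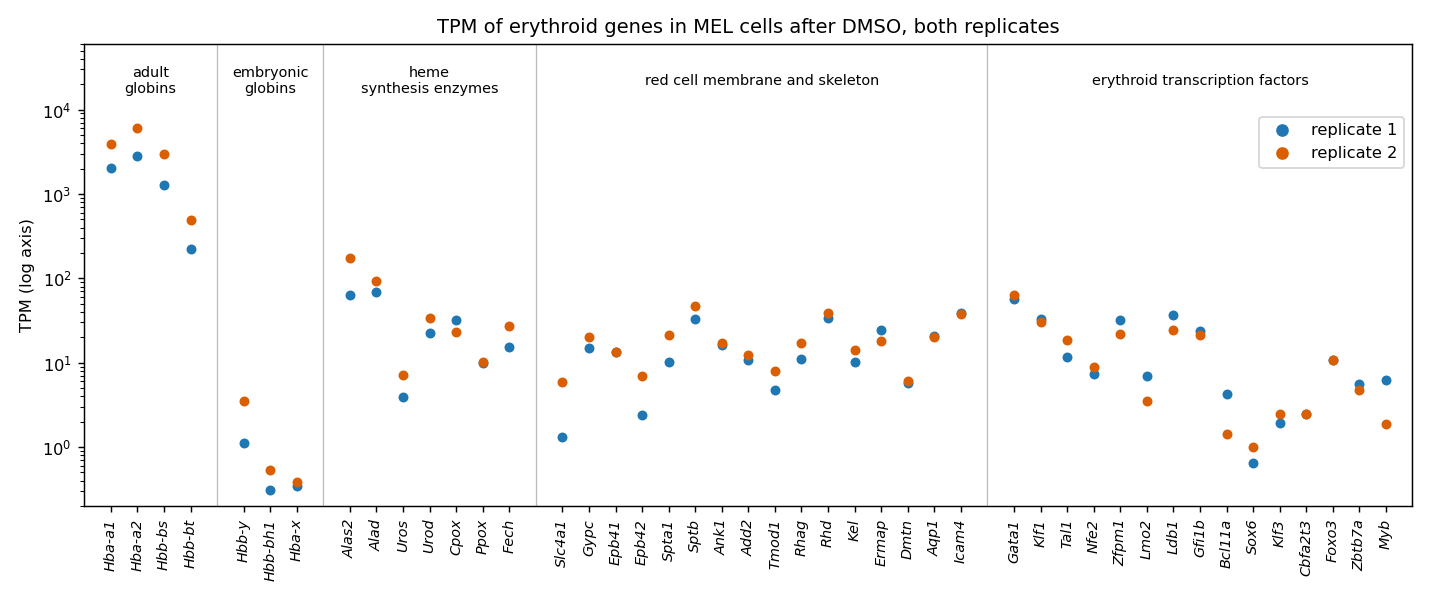
TPM on a log axis of genes of 5 erythroid lists, with replicate 1 in blue and replicate 2 in orange. The 4 adult globin genes lie between 224 and 5997 TPM, and the 3 embryonic globin genes between 0.310 and 3.49 TPM.

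Erythroid transcription factors had a median of 7.43 TPM in replicate 1 and 8.83 in replicate 2, above the 99th percentile of random lists. Gata1 (chromosome X, 7959260 to 7978071), the central regulator of red cell genes, was the highest with 60.8 ± 4.86 TPM (SD, n = 2), ahead of Klf1 with 31.8 ± 1.54, Ldb1 with 30.9 ± 8.85 and Zfpm1 with 26.8 ± 6.94. Sox6, a repressor of embryonic globin, was the lowest with 0.820 ± 0.240 TPM. Transcription factors of progenitor and myeloid cells had a median of 1.40 TPM in replicate 1 and 0.920 in replicate 2, at the 28.2 and 21.8 percentiles. Of these, Gata2, which acts before Gata1 in red cell formation, stood at 0.250 ± 0.0283 TPM, so that Gata1 was at 246 ± 47.3 times its level. Spi1, the factor PU.1 of myeloid cells and a known oncogene of this leukemia, stood at 4.68 ± 0.537 TPM, and Gata1 was at 13.1 ± 2.55 times that level. Myc was at 10.3 ± 4.23 TPM and Lyl1 at 9.15 ± 0.948, while Hoxa9 and Hhex were at 0 counts in both libraries.

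Markers of other blood and tissue cells were low, with exceptions among genes of megakaryocytes, the platelet-forming cells. None of the 5 progenitor surface markers, 8 mast cell and basophil markers, 12 lymphoid markers and 12 stromal and epithelial markers reached 1 TPM in both libraries. Protein-coding genes held only 13.2% of the summed TPM, so 1 TPM is a stricter cutoff here than in a table of mRNA alone. A gene below it is not shown to be absent. Kit, the stem cell factor receptor, had 12 counts in replicate 1 and 7 in replicate 2. Mpo, a granule enzyme of neutrophils, had 9 counts in each library, and the mast cell protease gene Cpa3 had 2 and 0. Of the stromal list, Col1a1, a collagen of connective tissue, had 102 counts in each library. The lymphoid list was led by the kinase gene Lck with 0.955 ± 0.445 TPM (SD, n = 2). Of 12 granulocyte and macrophage markers 1 reached 1 TPM in both libraries, the protease gene Prtn3 with 2.81 ± 1.33 TPM. Of 11 megakaryocyte markers 3 reached it: Pf4 (platelet factor 4) with 29.4 ± 6.63 TPM, the integrin gene Itga2b with 15.1 ± 5.67 and Gp5 with 1.51 ± 0.608.

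Genes of the cell cycle were expressed after 5 days of treatment. All 15 genes of S phase and replication and all 15 genes of G2 and mitosis were above 1 TPM in both libraries, with medians of 14.5 and 13.1 TPM and of 17.9 and 19.0 TPM for replicates 1 and 2. Top2a, the topoisomerase of dividing cells, stood at 88.7 ± 12.5 TPM (SD, n = 2), the sliding clamp gene Pcna at 58.4 ± 5.04 and the proliferation marker Mki67 at 32.8 ± 4.09. Among cell cycle inhibitors and D cyclins, Ccnd3 with 24.0 ± 1.49 TPM and Cdkn2a, which encodes the p16 and p19 tumor suppressors, with 20.5 ± 2.10 were the highest, while Cdkn1a was at 0.535 ± 0.0212 and Ccnd1 at 0.0300 TPM in both libraries. That list's median was 3.99 TPM in replicate 1 and 4.96 in replicate 2. All 13 genes of autophagy and mitophagy were expressed, with medians of 4.12 and 4.65 TPM, from Sqstm1 with 35.7 ± 7.04 TPM and Becn1 with 25.6 ± 1.73 down to Ulk1 with 1.69 ± 0.0566.

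Of 12 stress response genes, 6 reached 1 TPM in both libraries, among them the chaperone genes Hspa5 with 83.8 ± 39.6 TPM and Hsp90aa1 with 70.4 ± 24.9 (SD, n = 2), and the factor Atf4 with 44.7 ± 1.16. The heat shock genes Hspa1a and Hspa1b had at most 5 counts in either library. Widely expressed genes had a median of 70.0 TPM in replicate 1 and 61.1 in replicate 2. Of the list of X inactivation and Y-linked genes of the mouse line, the X inactivation RNA Xist had 2 and 7 counts, and the Y-linked genes Eif2s3y, Uty, Ddx3y and Kdm5d stood at 11.1 ± 0.820, 5.71 ± 0.361, 5.22 and 1.42 ± 0.00707 TPM.

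Transcript use was compared between the libraries because transcript tables accompany the gene tables. Of 6177 expressed genes with several annotated transcripts, 5735, or 92.8%, had the same most abundant transcript in both libraries. Among genes of the erythroid factor, heme and membrane lists, the most abundant transcript held the smallest share in the ankyrin gene Ank1, with 22.7% ± 4.13 (SD, n = 2), and it was a different transcript in each library. The band 4.1 gene Epb41 followed with 30.7% ± 0.735, Epb42 with 33.5% ± 2.35, Bcl11a with 33.9% ± 6.36 and Alas2 with 33.9% ± 0.375. For Alas2 the leading transcript also differed between the libraries, annotated as a processed transcript in replicate 1 (34.1%) and as protein-coding in replicate 2 (33.6%). The SD given for Ank1 and Alas2 is therefore not the spread of the share of any 1 transcript.

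The third question was which genes differed between the 2 libraries of the same condition. Red cell genes were higher in replicate 2 across several lists, but not in all. All 4 adult globin genes passed the test at 2-fold or more, with log2 ratios of replicate 2 to replicate 1 from 1.15 for Hba-a1 to 1.46 for Hbb-bs. Of 8 heme synthesis enzymes 4 passed, led by Alas2 with 1.78. Of 17 membrane and skeleton genes 5 passed, led by Slc4a1 with 2.79 (95% exact interval 2.70 to 2.88, counting error only) and the band 4.2 gene Epb42 with 1.82. Of 15 erythroid transcription factors 3 passed: Sox6 was higher in replicate 2 with 1.06, and Bcl11a, a repressor of embryonic globin, and Myb, a factor of proliferating progenitors, were lower with -1.17 and -1.46. Of 12 genes of iron and heme handling 0 passed, and at an adjusted p under 0.05 alone 5 were higher and 7 lower in replicate 2. Of 13 tested genes of red cell cytoplasm and maturation 0 passed. Beside these lists the makeup of the libraries differed. Annotated rRNA and the rRNA locus of chromosome 17 took 7.40% of the counts in replicate 1 (95% Wilson interval 7.395 to 7.408) and 2.70% in replicate 2 (2.701 to 2.708), and mitochondrial rRNA took 0.394% (0.393 to 0.396) and 0.215% (0.214 to 0.216).

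These calls come from an exact two-sided binomial test on rounded estimated counts after TMM scaling, with Benjamini-Hochberg adjustment. The test compares the reads of 2 libraries of 1 condition, not conditions, and it covers counting error only. Of 15272 genes tested, 9385 had an adjusted p under 0.05 by this test, and 963 also differed by 2-fold or more, 363 of them higher in replicate 2 and 600 higher in replicate 1. With 100 or more counts required in at least 1 library, 395 genes passed both thresholds. When the correction was adjusted over the list alone, the number of members past both thresholds was that found over all genes for each of the 23 lists.

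Relative to random lists matched on expression, the median log2 ratio on the TPM + 1 scale lay at the 100th percentile for adult globins (1.11), heme synthesis enzymes (0.64), membrane and skeleton genes (0.41) and linker histones (0.47). The median of all expressed protein-coding genes was -0.20 on that scale and 0.04 on TMM-scaled counts, and list values are read against it. Genes of G2 and mitosis had a median of 0.11, also at the 100th percentile, and all 15 had an adjusted p under 0.05 in the binomial test with higher values in replicate 2, yet none reached 2-fold. Cell cycle inhibitors and D cyclins (0.01, at the 99.2 percentile), autophagy genes (0.06, at 99.9), embryonic globins (0.23, at 99.7) and RNAs without a poly(A) tail (0.12, at 98.1) were also above the central 95% of matched lists. Of the embryonic globins, Hbb-y and Hbb-bh1 passed the test with log2 ratios of 1.91 and 1.06.

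The other 14 lists stayed within the central 95% on this scale. Iron and heme handling lay at the 3.21 percentile with a median of -0.36, and on TMM-scaled counts it lay outside, at the 0.69 percentile with -0.17, but at the 41.0 percentile with a pseudocount of 10. S phase genes lay at the 5.75 percentile with -0.41, and at 3.42 with -0.09 on TMM-scaled counts. Red cell cytoplasm genes lay at the 95.2 percentile with a median of -0.02 and erythroid transcription factors at 93.5 with -0.10; on TMM-scaled counts they lay at 97.1 and 87.0, with medians of 0.23 and 0.18 against the shifted baseline. Widely expressed genes lay at the 21.4 percentile and transcription factors of progenitors and myeloid cells at 33.9; on TMM-scaled counts these lay at 14.3 and 67.8. Stress response genes lay at the 97.3 percentile, and 2 of 9 tested passed, the pseudokinase gene Trib3 with a log2 ratio of 1.40 and Atf3 with 1.72. Megakaryocyte markers lay at the 96.0 percentile with Itga2b at 1.12 and its partner Itgb3 at 1.15 past the test. The medians of granulocyte, lymphoid, stromal, mast cell and progenitor surface markers lay at the 92.5, 91.6, 91.1, 85.5 and 76.7 percentiles with log2 medians of 0.00, set by ties of members near 0 TPM, and of their members the keratin gene Krt8 passed, with 27 counts in replicate 1 and 14 in replicate 2. The list of X inactivation and Y-linked genes lay at the 92.1 percentile.

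**Figure D3:**
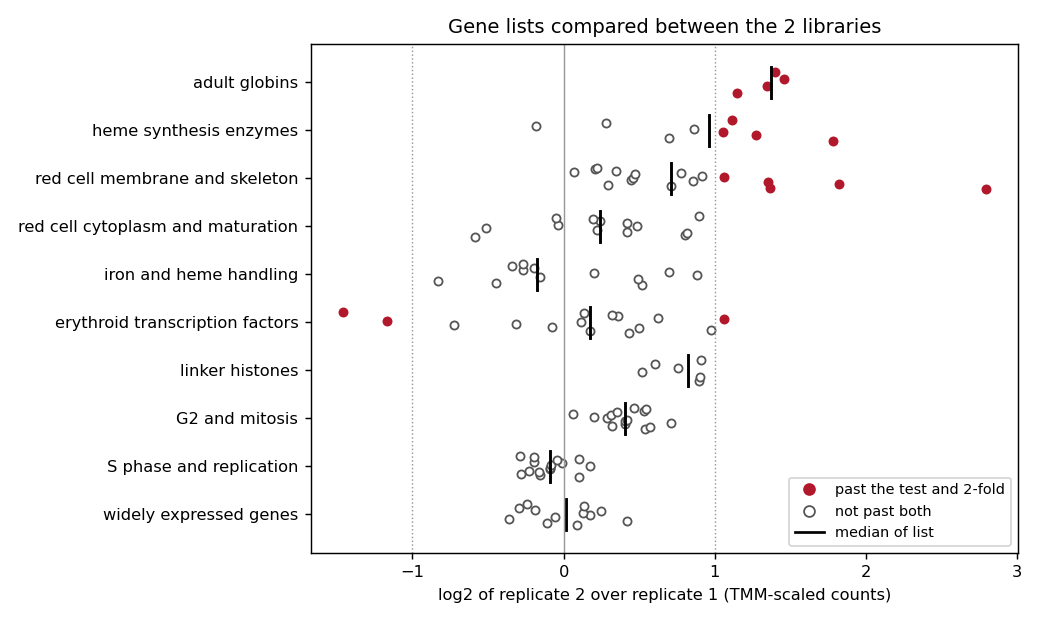
Log2 ratio of replicate 2 to replicate 1 on TMM-scaled counts for each tested gene of 10 lists; filled red points passed the binomial test at 2-fold or more, open points did not, black bars are list medians and dotted lines mark 2-fold. The adult globins lie between 1.15 and 1.46 and Slc4a1 at 2.79, while Myb lies at -1.46.

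Among the 10 genes with the largest ratios, 5 in each direction, 3 had a small posterior spread of their read assignment. Slc4a1 had 1100 counts in replicate 1 and 10412 in replicate 2, a 6.93-fold difference after scaling. Lars2 (chromosome 9, 123366927 to 123462666), the mitochondrial leucyl-tRNA synthetase gene, had 409566 counts in replicate 1 and 81725 in replicate 2, a log2 ratio of -2.77. The unnamed gene ENSMUSG00000045999 had 900645 and 172317 counts, a log2 ratio of -2.84. For the other 7, the authors' posterior spread exceeded 5% of the count in at least 1 library, and their values are uncertain. The processed pseudogene Gm4294 and the histone H3 gene Hist2h3c1 had 0 counts in replicate 1 and were at least 42.7-fold and 34.7-fold higher in replicate 2, and ENSMUSG00000090407 had 0.55 and 129 counts. ENSMUSG00000090234 and Gm31748 had 0 counts in replicate 2 and were at least 56.9-fold and 54.2-fold lower there. These bounds, and those of Gm4294 and Hist2h3c1, are against a floor of 3 counts per library and take the other count as exact. Gm10222 and Gm10925, neighbouring pseudogenes on chromosome 1 (24612407 to 24612700 and 24613974 to 24614651), differed in opposite directions, with log2 ratios of 5.39 and -8.09.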

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

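The tests of scaling and of maturation stage for the globin pattern and the test on Lars2 were chosen after the results were seen. Rows without a matched gene name held reads above the limit of 3 counts that a count of 0 allows, and no control library was there to set a background. The tRNA rows held 75 counts in replicate 1 and 164 in replicate 2. Gene rows whose identifiers had no match in the later annotation held 1879140 and 669421 counts. Most of these lay in ENSMUSG00000045999, with 900645 counts in replicate 1 and 172317 in replicate 2, and ENSMUSG00000103057, with 882199 and 365382.

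The first pattern was that RNAs under 200 nt held 44.8% ± 0.764 (SD, n = 2) of the summed TPM but 1.65% ± 0.118 of the estimated counts. When counts were divided by the annotated length in place of the effective length, the share fell to 7.45% ± 0.142. The effective length of the 144-nt snoRNA Gm25835, for example, was 2.90 nt in replicate 1 and 1.76 nt in replicate 2, and such small divisors may account for most of the TPM share. Genuine abundance of snRNA and snoRNA in total RNA stays open for the rest. No biological explanation was tested, because the design holds 1 condition.

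The second pattern was the higher level of adult globin, heme synthesis and membrane genes in replicate 2, beside a lower share of the rRNA class, 2.70% of the counts against 7.40%. Different scaling of the libraries was tested by rescaling TPM over nuclear protein-coding genes without adult globins. The median log2 ratio of these 29 genes was then 0.72, and 27 of the 29 were above 0. That rescaling also raised the median of expressed protein-coding genes, from -0.20 on the TPM + 1 scale to -0.11. It raised ratios in general and could not have lowered those of the 29 genes, so this test cannot decide. Scaling alone would move all genes together, while the 29 genes stood above that median. These lists were taken because they were high in these same data, so the count of 27 and this gap in part repeat the choice. Among the other red cell lists after the same rescaling, iron and heme handling had a median of -0.34 and cytoplasm and maturation 0.12. Transcription factors had 0.048 and embryonic globins 0.73, against -0.11 for expressed protein-coding genes. On the TPM + 1 scale before rescaling these medians were -0.36, -0.02, -0.10 and 0.23 in that order, against -0.20. At an adjusted p under 0.05 in the binomial test, 9 cytoplasm genes were higher and 2 lower in replicate 2. For transcription factors these numbers were 10 and 5, and for iron and heme handling 5 and 7. Transcript length and GC content are argued against, since the median of the 29 genes lay at the 100th percentile of random lists matched on expression, length and GC. A candidate explanation is that the cells of replicate 2 had gone further in red cell maturation. The 6 expressed transcription factors of progenitors and myeloid cells lay at the 22.3 percentile of matched lists. The whole list went from 33.9 to 67.8 on TMM-scaled counts and 92.7 after rescaling. On TMM-scaled counts its median of 0.00 was set by Hoxa9 and Hhex, which had 0 counts in both libraries. These values do not decide, so this explanation stays open, as does a difference in RNA preparation that goes with the rRNA share.

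The third pattern was the gene Lars2, 6.84-fold lower in replicate 2. Gm42418 (chromosome 17, 39846958 to 39848788), which overlaps the annotated rRNA gene CT010467.1, was 5.81-fold lower, and its log2 ratio of -2.54 differed from that of Lars2 by 0.24, while Gm26917, the other and more abundant gene of that locus, had -1.30 and differed by 1.48. Reads of rRNA counted at Lars2 could account for a shared difference in rRNA carry-over. Yet 0 of the 11129 different 21-base words of the Lars2 transcripts occurred in the annotated transcripts of that locus, which cover only part of the rRNA, so the explanation stays open. No biological explanation was tested, because both libraries are of 1 condition.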

How the results depend on the processing

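The number of expressed genes depended on the threshold: against 8564 at 1 TPM it was 12411 at 0.1 TPM, 11044 at an FPKM of 1 and 3461 at 5 TPM. Without 1 library it ranged from 8651 to 9195. The globin share moved from 0.986% of TPM to 1.88% of counts, to 7.67% of the TPM of nuclear protein-coding genes and, in an alternative chosen after seeing the data, to 1.78% of the TPM of genes of 200 nt or longer, since each has another denominator. Without 1 library it ranged from 0.636% to 1.34%. The alpha to beta ratio was 2.43 by counts, which are not divided by effective length. In replicate 1 the effective lengths of Hba-a2 and Hba-a1, 400 and 495 nt, were below the 552 nt of Hbb-bs. The ratio was 3.76 over protein-coding transcripts, with the cause not tested, and 2.89 to 3.26 without 1 library. The embryonic share of globin was 0.0342% by counts, again without division by effective length, and 0.0278% to 0.0331% without 1 library. The coefficient of variation stayed between 0.202 and 0.217. The 963 genes that differ became 962 with DESeq2 size factors, 997 with total counts and 944 with no filter. With a minimum of 100 counts 395 passed, 380 of them among the 963. That minimum left 11593 of 15272 genes to test, and the share called fell from 6.31% to 3.41%. The 10 genes named for the largest ratios passed under these alternatives. Of 23 lists, 11 lay above the 95th percentile in both libraries, 10 or 11 with another pool or unit, and 11 to 14 with 1 library; against the pool of all expressed genes, 16 list percentiles moved, all 16 lower, among them progenitor and myeloid factors from a mean of 25.0 to 0 and embryonic globins from 22.8 to 0.005. Lists outside the central 95% of matched lists numbered 9, 9 or 10 with other pseudocounts, 10 with TMM-scaled counts, and 17 after rescaling without adult globins. Of the 8 added, 6 had medians of 0.00 in both settings, so that ties at 0 set their percentile; for the others the cause was not tested. No list outside the central 95% in either setting changed sides. Iron and heme handling, at the 3.21 percentile, went below it to 0.66 with a pseudocount of 0.1, 0.54 after rescaling and 0.69 with TMM-scaled counts, the last chosen after seeing the data, but lay at 41.0 with a pseudocount of 10. The share of genes with the same leading transcript was 94.9% at 10 TPM. No paired analysis was possible because the labels give only 1 group. Depth limits genes near 3 counts, and with 2 libraries every SD is itself uncertain.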

Other observations

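The genes in this part were chosen after their values were seen. Beyond the named lists, several protein-coding genes with certain read assignment differed between the 2 libraries by more than 3-fold on TMM-scaled counts. Higher in replicate 2 were Nupr1, a stress-induced nuclear protein gene, with 138 counts in replicate 1 and 853 in replicate 2 (log2 ratio 2.17), the adaptor gene Grap2 with 795 and 4204 counts (1.95), and Abca4, a lipid transporter gene known from the retina, with 70 and 522 counts (2.44). Higher in replicate 1 were the glycolytic enzyme gene Hk2 with 5524 and 1850 counts (-2.03), the anion transporter gene Slc26a1 with 1534 and 485 (-2.11), the pseudokinase gene Trib2 with 1286 and 442 (-1.99) and the ETS factor gene Etv4 with 109 and 30 (-2.29). By TPM, Abca4 stood at 0.24 in replicate 1 and 0.61 in replicate 2, and Etv4 at 0.26 and 0.04, all under 1 TPM. Myc, a member of the progenitor and myeloid factor list, had 6405 counts in replicate 1 and 5835 in replicate 2. Its log2 ratio of -0.58 was short of 2-fold and in the same direction as Myb. Of that list, 2 members were higher and 2 lower in replicate 2 at an adjusted p under 0.05 in the binomial test.

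Gm26917 (chromosome 17, 39843013 to 39846341), a gene annotated as lincRNA that ends 11 bases before the annotated rRNA gene CT010467.1, held 4128538 counts in replicate 1 and 2295231 in replicate 2. It was 2.46-fold lower in replicate 2, less than the 5.81-fold of its neighbour Gm42418.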
